A study of Salmonella enterica subsp. enterica serovar Typhimurium with 4 samples.

How the data were processed

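RNA sequencing libraries from 4 cultures were analysed, 1 per group. The groups were a control and a nitrite culture harvested after 10 min (shock), and a control and a nitrite culture harvested at an OD600 of 1.45 to 1.55 (adaptation). Group membership was taken from the sample titles. Per the labels' protocols, total RNA was depleted of 16S and 23S ribosomal RNA by hybridisation, treated with DNase, fragmented with RNase III and made into barcoded libraries with a SOLiD total RNA kit. The shock and adaptation libraries were sequenced in independent runs of a SOLiD 5500xl, on 3 and 6 lanes, along with additional libraries of other work that are not analysed here. Per the submitters' processing notes, Bowtie, edgeR and R 3.0.2 were used; versions of Bowtie and edgeR, mapping settings, the treatment of multiply mapping reads, the use of strand in counting and the genome sequence are not given in the sources used here. Overlapping and antisense genes, and near-identical copies, are therefore uncertain where reads were shared between them.

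Of each pair the authors deposited 1 table with the same 5416 genes, 3307 of them with a gene symbol and 2109 with only a locus tag. Per the file headers, the authors deposited raw read counts per gene for control and nitrite. These are whole numbers whose sums match the library totals stated in the headers. A second set of columns is, per the file headers, CPM (counts per 1e+06 counts) rounded to whole numbers by the authors, so they were treated as a score and used only to check the counts; they differed from CPM recomputed from the counts by at most 0.500. Per the file headers, the authors also gave log2 fold changes from edgeR and Benjamini-Hochberg adjusted p-values for 3095 genes (shock) and 3080 genes (adaptation). The larger rounded CPM was at least 10 in genes with such values and at most 10 in genes without. No product in the tables names a ribosomal or transfer RNA gene, and 0 columns belonged to other samples. The most abundant gene, lpp, took 13.2% to 16.8% of each library, and the 20 most abundant genes together took 39.4% to 46.1%.

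Each nitrite library was compared with its own control. Genes with at least 20 counts over the pair were kept (4348 shock, 4900 adaptation). Libraries were scaled within the pair by TMM factors (edgeR 4.0.16 in R 4.3.3), which were 0.846 and 1.18 for the control and nitrite libraries of the shock pair and 0.980 and 1.02 for those of the adaptation pair. The log2 fold change is that of CPM with a prior of 0.5 counts scaled by library size. A gene was counted as higher or lower where the fold change was at least 2 and the exact 95% Clopper-Pearson interval of the ratio of its scaled counts excluded a ratio of 1. Such intervals and floors cover counting error only, since PCR copies are not independent molecules and the variation between cultures was not measured. The median width of an interval was 0.68 (shock) and 0.41 (adaptation) in log2 units. A count of 0 allows up to 3 counts, which is 0.469 and 0.315 CPM in the shock control and nitrite libraries, and 0.0832 and 0.155 CPM in the adaptation control and nitrite libraries. Folds against a count of 0 are bounds at that floor.

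Before the data were examined, 36 gene lists, the comparisons, the thresholds, the processing alternatives and a rule for named genes were fixed. Of 894 list entries 846 matched a gene of the tables, 16 of them through the product text or an older symbol because the tables give no symbol or an older one. The rule took, per comparison, the 10 highest and 10 lowest fold changes among genes at least 2-fold apart with at least 100 counts in the larger library, up to 4 members of each list, always hmpA, norV, nrfA and ytfE, and up to 10 genes with the largest difference among those at least 2-fold apart in opposite directions. That difference was taken between fitted values, also for genes with 0 counts in 1 library. For each list the median log2 fold change was placed among the medians of 10000 random lists of the same size, matched in 10 bins of mean expression. This percentile describes these libraries and is not a p-value. Random lists drew genes singly, so they did not keep neighbouring genes together. The counting error of a list median was taken from 200 Poisson draws of the counts. Overlaps are given beside the product of list sizes divided by the number of genes measured in both comparisons. The comparisons use different controls, so they share no control values.

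The procedure was tested on simulated counts with the share of each gene pooled over its pair and the real library sizes. In the shock simulation (4345 genes) 100 of 100 genes changed 4-fold and 99 of 100 changed 3-fold were called, as were 16 of 4145 unchanged genes, and intervals covered the true value in 95.8% of genes. In the adaptation simulation (4897 genes) these numbers were 100 of 100, 100 of 100 and 14 of 4697, and the coverage was 95.6%. These simulations hold counting error and no variation between cultures. The changed genes were drawn from genes with at least 100 counts over the pair, with equal numbers raised and lowered. Recovery was therefore not tested for genes of fewer counts, nor with as many changed genes as were called in the shock pair.

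Alternatives were median-of-ratios factors (DESeq2 1.42.0), total counts, upper-quartile factors, total counts without the 20 most abundant genes, count minimums of 1 and of 100, a prior of 5 counts, and the authors' deposited fold changes. A test of a nitrite effect shared by both pairs, chosen after seeing the data, used a model with pair and nitrite terms in edgeR (quasi-likelihood) and limma-voom (limma 3.58.1) on genes with at least 20 counts in each pair. For coding length, symbols were matched to the annotation of the LT2 strain (assembly ASM694v2), a different strain, whose coordinates were not used. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.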

Results

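The transcriptome of Salmonella enterica serovar Typhimurium strain 14028, an enteric pathogen, was measured by RNA sequencing in 4 cultures. All were grown at 24 °C in LB medium that had been brought to pH 5.5 with lactic acid, so that added nitrite was acidified in the medium. Acidified nitrite gives rise to nitric oxide and other reactive nitrogen species. In 1 culture sodium nitrite (150 mg/l) acted for 10 min, after addition at an optical density (OD600) of 0.83, and the comparison with its control asks for the shock response. In another culture the same dose was added at an OD600 of 0.85 and cells were harvested 1.5 to 2.0 h later at an OD600 of 1.46, beside a control harvested at 1.47, and this comparison asks for the response of cells that had adapted. The group size was 1 culture and 1 library throughout. No difference within a pair therefore has a replicate check or a p-value that rests on replicate cultures. Intervals given with fold changes are exact 95% intervals for counting error only. Total gene counts were 7569858 and 8060426 in the control and nitrite libraries of the 10 min pair, and 36809492 and 18921108 in those of the later pair.

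After 10 min with nitrite, genes of nitric oxide detoxification had some of the highest fold changes. The flavorubredoxin of the anaerobic nitric oxide reductase, norV (STM14_3431), was at a normalised level of 4.84 CPM (counts per 1e+06 counts after scaling) in the control library and 1671 CPM in the nitrite library, a 341-fold higher level (log2 fold change 8.41, interval 7.93 to 8.99). Its partner gene ygbD (norW) was 173-fold higher, and hmpA, which encodes the nitric oxide dioxygenase, was 89.0-fold higher at 2258 CPM (log2 fold change 6.48, interval 6.26 to 6.71). Also higher were ytfE, a gene for repair of damaged iron-sulfur centres, by 65.6-fold, and ygbA, of unknown function, by 38.5-fold. Of 14 measured genes in the list of nitric oxide responsive genes, 10 were at least 2-fold higher and 0 were at least 2-fold lower. The median log2 fold change of this list was 2.38, above all 10000 random lists of the same size and similar expression.

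Decarboxylase systems that consume protons accompanied them. The arginine decarboxylase gene adi was 41.6-fold higher in the nitrite library and its antiporter gene yjdE 16.1-fold higher. The lysine decarboxylase gene cadA was 17.7-fold higher and its antiporter gene cadB 27.4-fold higher. The acid resistance list as a whole went both ways, with 7 of 19 measured members at least 2-fold higher and 6 at least 2-fold lower, and its median of 0.17 (0.66 with total counts alone, 0.53 without the 20 most abundant genes) lay at percentile 80.3 of random lists. The remaining genes with the 10 highest fold changes were STM14_2185, annotated as a putative cytoplasmic protein (99.7-fold higher), and the hypothetical gene STM14_3199 (log2 fold change 4.17).

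Genes of the general stress response, many of which depend on the sigma factor RpoS, were also higher after 10 min. In this list 23 of 36 measured members were at least 2-fold higher and 0 at least 2-fold lower, with a median of 1.27 above all 10000 random lists. Examples are ycgB (8.24-fold), the peroxiredoxin gene osmC (7.70-fold), uspB (4.73-fold) and yeaG (4.42-fold). Compatible solute genes had a median of 0.94 (percentile 98.9; 1.42 with total counts alone), led by the proline and glycine betaine transporter gene proP (4.27-fold) and yehZ (3.55-fold). Iron-sulfur cluster assembly genes had a median of 0.52 (percentile 97.9; 1.01 with total counts alone), with sufA 5.04-fold and sufB 3.48-fold higher. Anaerobic metabolism genes had a median of 0.48 (percentile 99.4; 0.96 with total counts alone), with 12 of 47 measured members at least 2-fold higher against 1 at least 2-fold lower. In that list glpB was 7.50-fold higher, on 7 and 82 counts, and tdcB 3.58-fold higher. The propanediol and ethanolamine list had a median of 0.95 (percentile 98.4), but only 8 of its 40 listed genes had enough counts, with pocR 3.01-fold higher. Without a count minimum that median became 0.26, and with the authors' deposited fold changes 1.61.

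**Figure D1:**
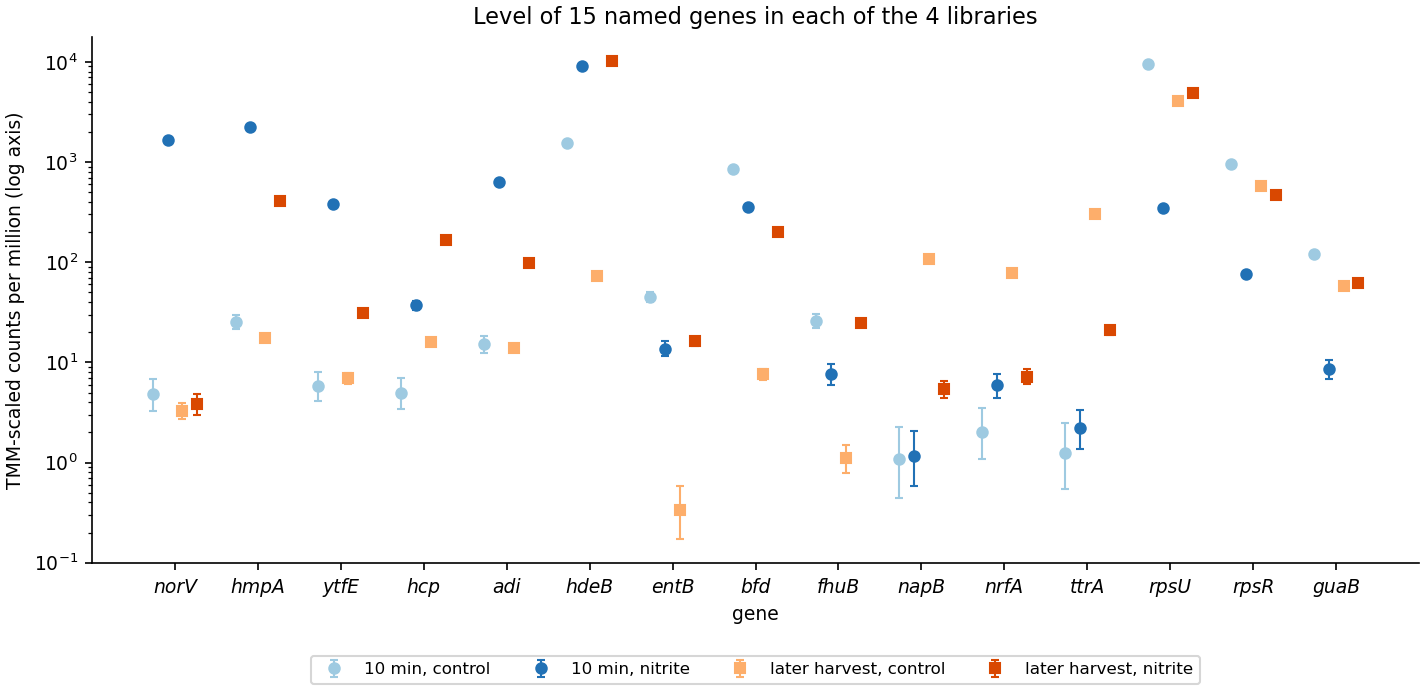
Level of 15 named genes in each of the 4 libraries, in CPM after TMM scaling within each pair (log axis), with bars for exact 95% Poisson counting intervals and 1 library per point. norV was at 1671 CPM in the 10 min nitrite library and at 3.83 CPM in the later nitrite library, and napB was at 108.1 CPM in the later control and at 5.44 CPM in the later nitrite library; the pairs came from independent sequencing runs.

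Genes for the translation apparatus and for nucleotide synthesis were lower in the nitrite library of the 10 min pair. Of 53 ribosomal protein genes, 45 were at least 2-fold lower and 0 were at least 2-fold higher, with a median log2 fold change of -2.16, below all 10000 random lists. The gene of ribosomal protein S21, rpsU, was 27.8-fold lower (9573 CPM against 345 CPM), rpsR 12.7-fold lower, rpsF 10.5-fold lower and rpsH 10.1-fold lower. Outside the list, rpsV, annotated as ribosomal subunit S22 and chosen after its values were seen, was 3.55-fold higher. Of 22 measured genes of purine and pyrimidine synthesis, 20 were at least 2-fold lower, with a median of -2.12 below all random lists. Among them guaB, for the first step from IMP to GMP, had a log2 fold change of -3.81, while pyrE was 10.1-fold and purB 9.03-fold lower. The carbamoyl phosphate synthase gene carA, shared by arginine and pyrimidine synthesis, was 27.0-fold lower, while argC and argE of arginine synthesis were 7.35-fold and 2.87-fold higher.

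ATP synthase genes were lower as well, with 7 of 9 at least 2-fold lower and a median of -1.26 (percentile 1.76; -0.78 with total counts alone). For the flagellar and chemotaxis list the median was -0.58 (percentile 0.11; -0.10 with total counts alone), and 24 of 56 members were at least 2-fold lower against 5 at least 2-fold higher. The basal body genes fliE, flgH and flgA were 7.33-fold, 6.87-fold and 6.84-fold lower. Genes under the PhoP and PmrA regulators, which modify the envelope, had a median of -0.90 (percentile 0.08; -0.43 with total counts alone), with virK 10.5-fold and pagP 7.46-fold lower. Genes of the invasion island SPI-1 had a median of -0.37 (percentile 1.32), which turned to 0.11 with total counts alone. Of 37 measured members 8 were at least 2-fold lower and 3 at least 2-fold higher. Within that list the export gene orgB was 6.55-fold lower, while the regulator genes sprB and hilC were 5.01-fold and 3.75-fold higher. The other genes with the 10 lowest fold changes were STM14_0296, STM14_4797 and STM14_4970 (45.1-fold to 51.0-fold), STM14_2489, yfdH, STM14_2562, ycaD and ptpS (15.9-fold to 27.7-fold). The hypothetical genes STM14_0296, STM14_4797 and STM14_4970 had near-equal counts in each library (1259 to 1323 in the 10 min control), so their values are uncertain if they are copies that share reads.

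Over all 4348 genes with enough counts, 656 (15.1%) were at least 2-fold higher after 10 min with nitrite and 785 (18.1%) at least 2-fold lower, of which 135 and 223 differed at least 4-fold. The split depended on scaling. Higher genes made up 45.5% of the genes at least 2-fold apart with TMM factors, 74.9% with total counts alone (1272 higher, 426 lower) and 68.2% with total counts after leaving out the 20 most abundant genes (1086 higher, 506 lower). In the authors' deposited table, which gives a value for 3095 genes, 515 were at least 2-fold higher and 619 at least 2-fold lower. With 1 library per arm the adjusted p-values in that table hold no measured variation between cultures, so they do not test the conditions.

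At the later harvest, iron acquisition genes were higher in the nitrite library than in its control. Of 39 measured members, 31 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 fold change of 2.67, above all 10000 random lists. The enterobactin synthesis gene entB was 46.1-fold higher (0.333 CPM against 16.2 CPM, log2 fold change 5.53, interval 4.78 to 6.57) on 12 and 312 counts, and entA was 23.1-fold higher. Among transport genes, fepC for enterobactin was 22.2-fold higher and fhuB for hydroxamates 21.7-fold higher. The ferredoxin gene bfd, which serves iron release from bacterioferritin, was 26.3-fold higher, and ybdB and ybdZ of the enterobactin cluster were 23.5-fold and 27.6-fold higher. In the control library ybdB and ybdZ had only 12 and 6 counts, and the intervals of their log2 fold changes were 3.78 to 5.61 and 3.76 to 6.41.

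Among genes with at least 100 counts, the highest fold change of the later pair was that of hdeB, a periplasmic acid resistance chaperone, with 73.2 CPM in the control and 10225 CPM in the nitrite library (139.7-fold; log2 fold change 7.13, interval 7.07 to 7.18). In the acid resistance list 6 of 19 members were at least 2-fold higher and 1 was at least 2-fold lower, with a median of 0.23 (percentile 97.6). With upper-quartile factors that median was 0.21, inside the range of random lists in the main setting. Besides hdeB, yjdE was 12.0-fold, the putrescine transporter gene potE 10.6-fold and the ornithine decarboxylase gene speF 9.40-fold higher.

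Most genes of the nitric oxide list were still higher at this time, with 8 of 14 at least 2-fold higher and a median of 1.79 above all random lists. There hmpA was 23.2-fold, ygbA 18.4-fold, hcp (hydroxylamine reductase) 10.4-fold, yeaR 10.3-fold and ytfE 4.46-fold higher. By contrast, norV had 3.27 CPM in the control and 3.83 CPM in the nitrite library, and the interval of its log2 fold change (-0.21 to 0.66) included 0. The 2 other genes with the 10 highest fold changes were STM14_2185 (21.1-fold) and the hypothetical gene STM14_2271 (18.7-fold). Iron-sulfur assembly genes had a median of 0.43 (percentile 99.9), with sufA 7.33-fold and sufS 4.14-fold higher. Positive medians were also found for flagellar and chemotaxis genes (0.46, above all random lists, 5 of 56 at least 2-fold higher). Curli and cellulose genes had a median of 0.66 (percentile 99.4, on 8 measured genes, and 0.42 with a minimum of 100 counts). Multidrug efflux genes had a median of 0.34 (percentile 99.2, 3 of 16 at least 2-fold higher and 1 lower). That median was 0.23 with a minimum of 100 counts, below the upper bound of 0.27 of random lists in the main setting. The 3 higher efflux genes, yegO (5.05-fold), yegN and STM14_2624, are neighbours. The ribonucleotide reductase gene nrdH had 3 counts in the control and 68 in the nitrite library, a log2 ratio of 5.13 with an interval of 3.79 to 7.72.

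**Figure D2:**
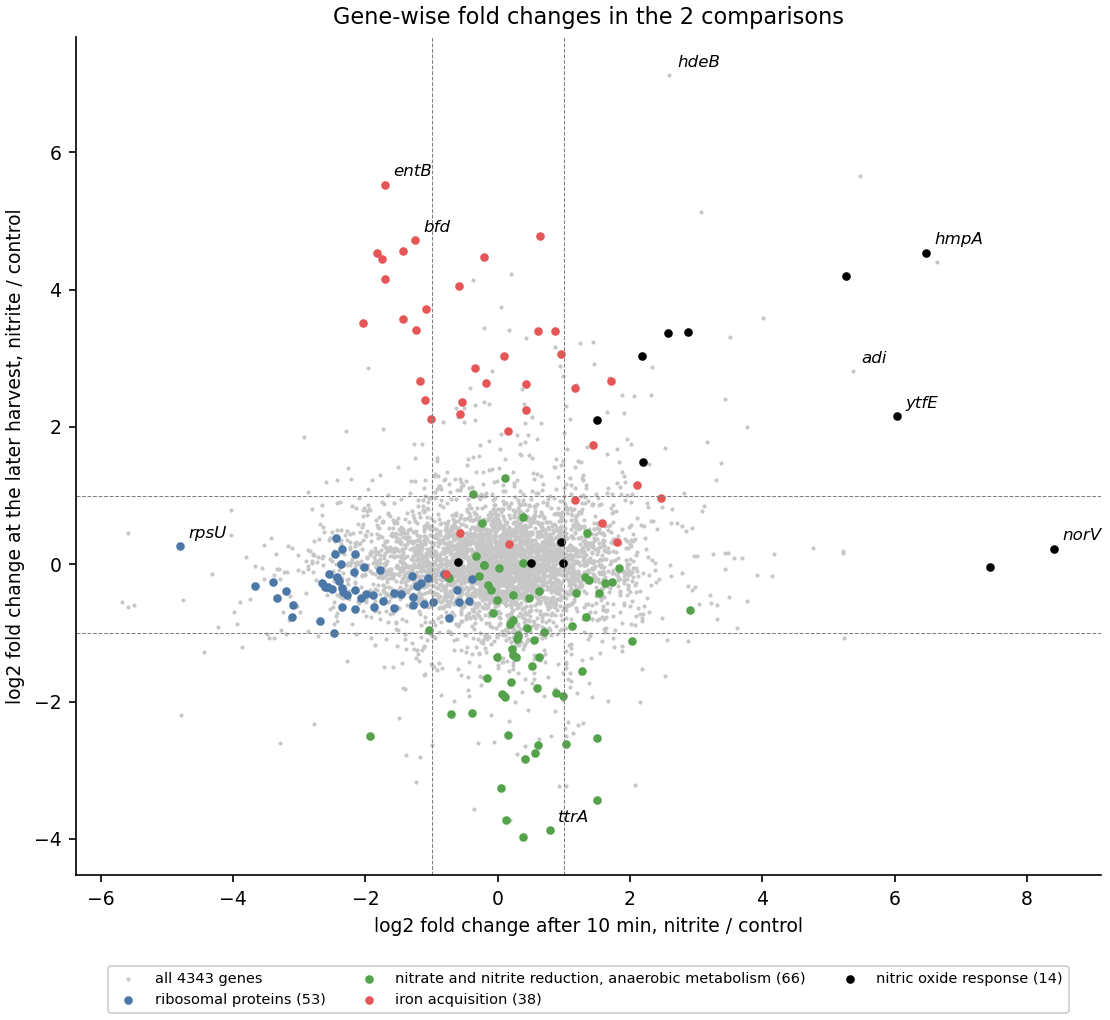
Log2 fold change after 10 min (x axis) against log2 fold change at the later harvest (y axis) for the 4343 genes measured in both comparisons; each point is 1 gene, colours mark gene lists, and dashed lines mark 2-fold differences. Ribosomal protein genes lie to the left (median -2.16 after 10 min), iron acquisition genes at the top (median 2.67 at the later harvest), and r across genes was 0.08.

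Lower at the later harvest were genes for respiration with acceptors other than oxygen. Of 29 genes of nitrate and nitrite reduction, 19 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -1.55 below all random lists (-2.51 with the authors' deposited fold changes, which cover fewer genes). The periplasmic nitrate reductase genes napG and napB were 19.9-fold and 19.8-fold lower, napC was 15.7-fold lower, and the nitrite reductase gene nrfA was 10.8-fold lower (log2 fold change -3.44, interval -3.70 to -3.19). Anaerobic metabolism genes had a median of -0.90, also below all random lists, and 24 of 55 were at least 2-fold lower against 4 at least 2-fold higher. In that list the dimethyl sulfoxide reductase gene dmsB was 23.0-fold and the tetrathionate reductase gene ttrA 14.7-fold lower. Genes for cytochrome c maturation were among the 10 lowest fold changes, namely ccmF_1 (19.8-fold, on 160 and 4 counts), ccmA_2 (13.8-fold, on 344 and 13 counts) and ccmH_2. That last gene had 129 counts in the control and 0 in the nitrite library and was at least 23.0-fold lower with the floor of 3 counts. The ccm genes are annotated at 2 loci, and values of such copies are uncertain where they share reads. STM14_5180, a putative subunit of a dimethyl sulfoxide reductase, had 194 counts in the control and 1 in the nitrite library (log2 ratio -6.27, interval -12.01 to -4.20), and the chaperone gene stcB of a fimbrial cluster was 17.9-fold lower.

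Other lists with a median below nearly all random lists were branched-chain amino acid synthesis (-0.41, percentile 0.37), ribosomal proteins (-0.37, percentile 0.025) and SPI-1 invasion (-0.25, percentile 0.66; -0.06 with the authors' deposited fold changes). Of these, branched-chain synthesis and ribosomal protein genes had 0 members at least 2-fold apart. In SPI-1, 6 of 40 members were at least 2-fold lower and 5 at least 2-fold higher, so these went both ways. There invF was 11.8-fold lower, while sprB and hilC were 5.52-fold and 4.62-fold higher, as both were after 10 min. Single genes of other lists were lower too, among them the catalase gene katG (5.20-fold), the porin gene ompW (4.91-fold) and the iron superoxide dismutase gene sodB (2.48-fold).

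At the later harvest 311 of 4900 genes (6.35%) were at least 2-fold higher with nitrite and 370 (7.55%) at least 2-fold lower, of which 108 and 111 differed at least 4-fold. The larger share depended on scaling, with 345 higher and 333 lower with total counts alone, and 372 and 299 without the 20 most abundant genes. With a minimum of 100 counts over the pair, 201 genes were at least 2-fold higher. In the authors' deposited table, which gives a value for 3080 genes, 136 were at least 2-fold higher and 188 at least 2-fold lower.

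**Figure D3:**
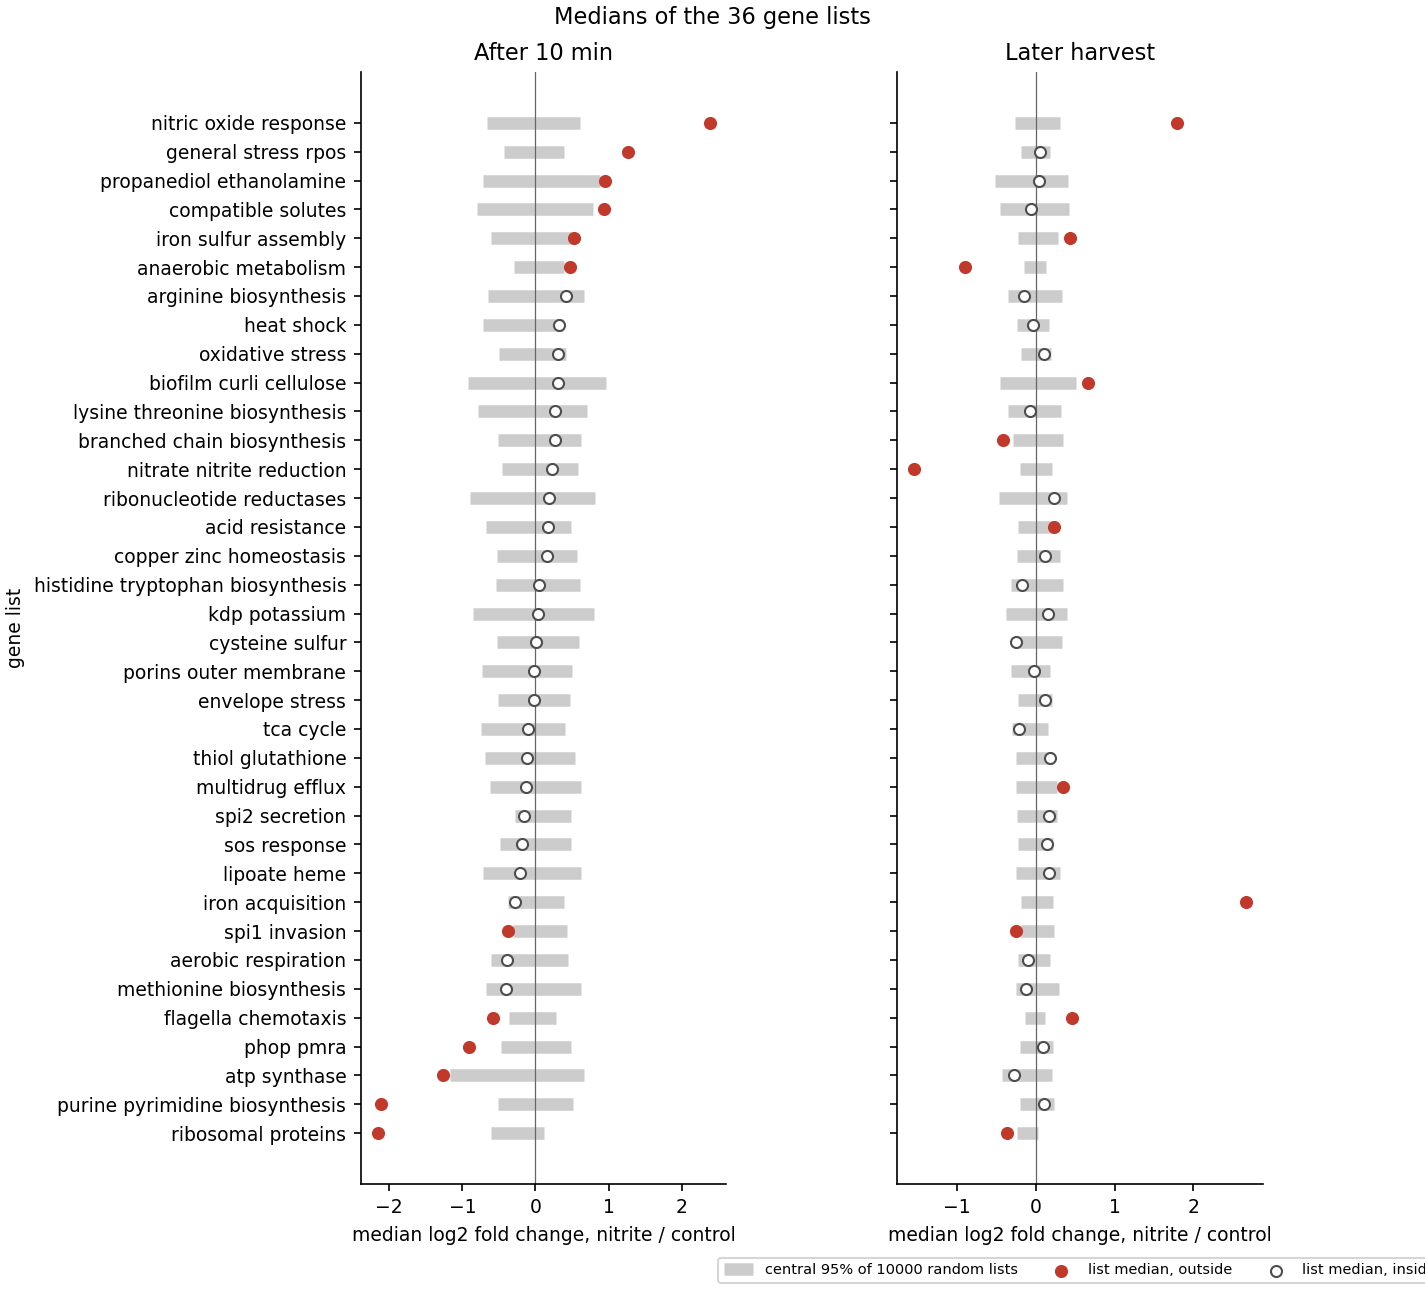
Median log2 fold change of each of the 36 gene lists (points) and the central 95% of medians of 10000 random lists of the same size and similar mean expression (grey bars), after 10 min (left) and at the later harvest (right). After 10 min 6 lists lay above and 6 below that range, and at the later harvest 7 above and 5 below.

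For the remaining 24 lists after 10 min the median lay within the central 95% of random lists, between -0.41 and 0.41. These include oxidative stress, thiol and glutathione, heat shock, SOS response, envelope stress, aerobic respiration and the tricarboxylic acid cycle. Iron acquisition was among them after 10 min, with a median of -0.27 (percentile 7.19; 0.21 with total counts alone), 8 members at least 2-fold higher and 13 at least 2-fold lower of 38 measured. At the later harvest 24 lists also lay within that range, between -0.28 and 0.24, among them general stress (0.06, percentile 75.5; 0.17 without the 20 most abundant genes) and purine and pyrimidine synthesis (0.10, percentile 78.2; 0.21 without those genes). If lists were random draws of single genes, 1.8 of 36 would lie outside the range in each comparison. Log2 fold changes of neighbouring genes were correlated (0.40 after 10 min and 0.47 later), and several lists hold many neighbours. For such lists the range can be too narrow and 1.8 too low. Some lists also share members, such as ytfE in nitric oxide response and iron-sulfur assembly, and otsA and otsB in general stress and compatible solutes. The medians of such lists are not separate results.

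In the main setting the 2 comparisons shared more higher genes than independent lists would, but no more lower genes. Of 4343 genes measured in both, 71 were at least 2-fold higher in both, where independent lists of these sizes would share 35.4, and 44 were at least 2-fold lower in both, where independent lists would share 44.6. The 71 included hmpA, ytfE, ygbA, hcp, yeaR, hdeB, yjdE and sufA. Across genes, which are not independent replicates, log2 fold changes of the 2 comparisons had a Pearson r of 0.08 and a Spearman rho of 0.03. With a minimum of 100 counts 65 genes were shared in the same direction in place of 115, and with the authors' deposited fold changes 56. The number that independent lists would share was not set beside these 65 and 56 genes. An excess over independent lists is therefore shown for the main setting only. A model with pair and nitrite terms over the 4 libraries, added after the data were seen, tested a nitrite effect shared by both pairs on 1 residual degree of freedom. At an adjusted p under 0.05, 0 of 4343 genes were higher and 0 lower by edgeR quasi-likelihood, and 0 and 0 by limma-voom. At an unadjusted p under 0.05, 88 were higher and 71 lower in edgeR and 102 and 74 in limma-voom. With the arms of 1 pair exchanged these counts were 73 and 52 in edgeR and 87 and 75 in limma-voom. That exchange asks for effects opposite in the 2 pairs, so its counts are not a level expected without any effect. The smallest adjusted p in edgeR, 0.209, was that of hmpA, ygbA, STM14_2161, STM14_2185 and yjdE, each higher with nitrite in both pairs, with a shared log2 fold change of 5.52 for hmpA. The smallest adjusted p in limma-voom, 0.0885, was that of hmpA, ygbA and STM14_2161. The residual of this model holds any difference between the early and the later response. The pairs differed in time after nitrite, growth stage, culture and sequencing run together, so none of these can be told apart as the source of a difference between them.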

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

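Results are listed here because a gene or gene list was at least 2-fold apart, or outside the central 95% of random lists, in opposite directions in the 2 comparisons. With 1 library per group the difference between the comparisons was not tested, and time after nitrite cannot be told apart from sequencing run. The test of low counts for the anaerobic genes was chosen only after its result was seen, and the list of Fur-dependent genes was written after the data were in hand.

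Of the 10 genes named for such a difference, 8 belong to the iron acquisition list and were lower after 10 min and higher at the later harvest. The whole list went both ways after 10 min, with 13 of 38 measured members at least 2-fold lower and 8 at least 2-fold higher. Among the higher members were iroB (5.52-fold), iroN (4.31-fold) and the neighbouring genes sitA to sitD. The log2 fold change after 10 min minus that at the later harvest was -7.23 for entB (-1.70 and 5.53), -6.35 for entA (-1.82 and 4.53), -6.19 for fhuB (-1.75 and 4.44) and -5.99 for ybdB (-1.43 and 4.56). It was -5.97 for bfd (-1.25 and 4.72), -5.87 for fhuD (-1.71 and 4.16), -5.55 for entE (-2.03 and 3.51) and -5.01 for entD (-1.43 and 3.57). With total counts alone the values of bfd, ybdB and entD after 10 min became -0.77, -0.96 and -0.95, still lower but by less than 2-fold. The hypothetical genes STM14_0580 and STM14_4951 went the other way. STM14_0580 had 0 and 22 counts after 10 min (at least 4.93-fold higher) and 40 and 10 counts later (-1.07, and -0.97 with total counts without the 20 most abundant genes), a difference of at least 3.37 at the floor of 3 counts; it was named by its fitted value over 0 counts, and at this bound other genes, nrfA among them, had larger differences. STM14_4951 had 4 and 27 counts after 10 min (2.07, interval 0.66 to 4.16) and 40 and 2 later (-3.21, interval -6.52 to -1.47), a difference of 5.29.

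Another 7 genes named in both comparisons also went opposite ways, as values with no test. Higher after 10 min and lower later were nrfA (1.50 and -3.44, a difference of 4.94), ompW (1.07 and -2.30, difference 3.36) and soxS (1.57 and -1.12, difference 2.69). Lower after 10 min and higher later were fliE (-2.87 and 1.05, difference -3.93), flhB (-2.60 and 1.20, difference -3.80), yegN (-1.14 and 1.76, difference -2.90) and lysA (-1.33 and 1.04, difference -2.36). With total counts alone the 10 min values of yegN and lysA became -0.67 and -0.86, lower by less than 2-fold, and with a prior of 5 counts the later value of lysA became 0.98.

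At the later harvest, iron acquisition genes were higher as a group. Few counts do not account for this, since the 19 members with at least 100 counts in each library of the pair had a median log2 fold change of 2.24, nor does library scaling, since the lowest median over 4 other scalings and the authors' fold changes was 2.65. A candidate explanation is lower activity of the iron regulator Fur than in the later control, which predicts lower expression of iron storage genes and iron-using enzymes. The 11 such genes had a median of -0.45, at percentile 0.835 of random lists. Of these, ftn (-2.81), fumB, sodB and bfr were at least 2-fold lower, and the other 7 were not counted as at least 2-fold apart. Relative to the 10 min control the iron acquisition median was -4.24 in the later control and -0.91 in the later nitrite library, so a lower level at the later time that nitrite lessened stays open, across sequencing runs and untested, as does the reason for either.

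Anaerobic metabolism genes differed by 1.37 between the comparisons, with medians of 0.48 after 10 min and -0.90 at the later harvest. Together with nitrate and nitrite reduction genes, 65 members with at least 500 counts had a median of -1.18 later, so few counts do not account for the lower level. The later nitrite library may have missed a rise that goes with growth. Against a wholly missing rise, the median log2 ratio to the 10 min control over 66 members was 1.62 in the later nitrite library (quartiles 0.88 and 3.17) and 2.60 in the later control, against 0.24 and 0.17 over all genes. These ratios cross sequencing runs, so a smaller rise with nitrite stays open, as do direct effects of nitrite on these genes.

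Flagellar and chemotaxis genes had medians of -0.58 after 10 min and 0.46 at the later harvest, a difference of -1.04; with total counts alone the first median became -0.10.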

How the results depend on the processing

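Of the shock counts, 656 higher and 785 lower genes became 1272 and 426 with total counts only, and 1086 and 506 with total counts without the 20 most abundant genes. These scalings moved the median log2 fold change of all genes by 0.48 and 0.35, so a direction near 0 in the shock pair holds only relative to the scaling. In the adaptation pair leaving out those genes moved that median by 0.11. Of the adaptation counts, 311 higher genes became 201 with a minimum of 100 counts and 136 with the authors' deposited fold changes, and 370 lower genes became 188 with the latter. The 115 genes shared in direction became 65 and 56 under these settings. Both settings test fewer genes by construction (4224 and 3080 in place of 4900). The correlation across genes, 0.08, became 0.10 with the authors' fold changes; the cause was not tested. Under the other alternatives these 2-fold and overlap counts stayed within 1.5 times the main count; the 4-fold counts, the overlap by direction and the member counts per list were not recomputed as alternatives. The SPI-1 median after 10 min, -0.37, became 0.11 with total counts only, by the shift of all genes. No other list outside the central 95% of random lists changed sign under any alternative run, while over all 36 lists 14 shock and 6 adaptation medians did. An unchanged sign does not mean that a list stayed outside that range, since random lists were not redrawn under the alternatives. Some medians moved inside the range of the main setting. At the later harvest these included multidrug efflux (0.23) and curli and cellulose (0.42) with a minimum of 100 counts, and SPI-1 (-0.06) with the authors' fold changes. Acid resistance at the later harvest, 0.232 against an upper bound of 0.228, was also among these medians, at 0.214 with upper-quartile factors. After 10 min they included propanediol and ethanolamine (0.26) without a count minimum. List medians moved beyond counting error in 80 shock and 36 adaptation cases. Of 217 named values at least 2-fold apart, 35 fell below that threshold in at least 1 alternative, and 0 changed sign. Depth limits genes of low count: 355 and 276 genes had 0 counts in the shock control and nitrite libraries. No paired analysis was possible because each comparison holds 1 pair of libraries, which leaves no test within it; the model over both pairs, chosen after seeing the data, asks only for a shared effect and gave 0 higher and 0 lower genes with either tool.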

Other observations

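The 3 tests of the ribosomal protein pattern, the runs of neighbouring genes, the ratios across sequencing runs and the genes outside the naming rule were chosen only after the data were seen.

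Genes with consecutive locus tags often shared their direction. Runs of at least 4 consecutive genes at least 2-fold apart the same way numbered 45 after 10 min (16 higher, 29 lower) and 30 at the later harvest (13 higher, 17 lower), while 1000 shuffles of the gene order gave at most 9 and 3. Log2 fold changes of neighbours had a correlation across genes of 0.40 and 0.47, against at most 0.053 and 0.045 in shuffled order. After 10 min, higher runs held glpQ, glpT and glpABC of glycerol phosphate use (6 genes, median 1.58), the dpp dipeptide transporter genes (5 genes, median 2.12) and citFEDC of citrate cleavage (4 genes, median 1.46). Lower runs held the rnf electron transport genes (10 genes from nth, median -2.06) and rfb genes of O antigen synthesis (7 genes, median -1.19). At the later harvest, higher runs held hydrogenase 1 and putative cytochrome oxidase genes (8 genes from STM14_2161, median 2.15), the ego and yne genes of sugar and autoinducer uptake (7 genes, median 2.34) and a cluster with arginine deiminase, carbamate kinase and ornithine carbamoyltransferase genes (6 genes from STM14_5356, median 2.80). Lower runs held hyb genes of hydrogenase 2 (8 genes, median -1.82), cbi genes of cobalamin synthesis (7 genes, median -1.45), men genes of menaquinone synthesis (5 genes, median -1.36) and stc fimbrial genes (5 genes, median -2.54).

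Several abundant genes outside the naming rule differed after 10 min. The gene yfiA of the ribosome-associated inhibitor RaiA was at 1784 CPM in the control and 21142 CPM in the nitrite library (11.9-fold higher). The leader peptide genes leuL and ilvL of branched-chain amino acid operons were 13.7-fold and 10.8-fold higher. Lower with nitrite were fis, of a nucleoid protein typical of fast growth (14.6-fold), infA of initiation factor IF-1 (11.8-fold) and cspE (10.8-fold). At the later harvest the log2 fold changes of yfiA, infA, cspE, leuL and ilvL lay between -0.54 and 0.38, and fis was 2.31-fold lower.

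Levels across the sequencing runs, scaled by total counts and given as median log2 ratios to the 10 min control, differed between lists. Iron acquisition genes stood at -4.24 in the later control and at -0.91 in the later nitrite library. Nitric oxide responsive genes stood at 0.55 and 2.38 in these libraries, and general stress genes at 0.35 and 0.38. Over all genes the ratios were 0.17 and 0.24.

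Ribosomal protein genes were lower after 10 min with a median log2 fold change of -2.16. Library scaling alone does not give this, since the highest median over 4 other scalings and the authors' fold changes was -1.68. Coding length does not give it either, since the median was below all 10000 random lists matched on length (percentile 0, all 53 members with a length). As a hypothesis, the lower level may be part of lower expression of the wider translation machinery. In a list without ribosomal proteins, 33 translation factor and aminoacyl-tRNA synthetase genes had a median of -1.16, below all random lists. Of these, 19 were at least 2-fold lower and 0 at least 2-fold higher. Neighbouring genes often shared their direction, so members that lie beside ribosomal protein genes are not independent of the pattern. A change in growth rate after nitrite was not measured within the 10 min, and with 1 culture per condition a difference between the cultures stays open.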
